A study of Mus musculus with 6 samples.

How the data were processed

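RNA was measured by sequencing in epithelium isolated from the esophagus of mouse embryos at stage E12.5. The labels give 3 p63KO samples, homozygous for a Trp63-CreERT2 allele, and 3 littermate controls. Per the labels' protocols, RNA was purified with the PicoPure kit and libraries were made with an Illumina TruSeq RNA kit and read for 100 bases. The labels name both single-end and paired-end reads, so the read layout is not resolved. Whether 1 sample is 1 embryo or a pool is not given in the sources used here, so p-values measure the spread between these samples.

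The deposited table holds raw counts per gene symbol, whole numbers with no normalization, for 23284 symbols in 6 columns. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0, DESeq2 (no version given) and the mouse build mm9 were used. The read counter, the annotation and the strand setting are not given in the sources used here. Reads of overlapping genes, antisense partners such as Tsix and Xist, and near-identical copies therefore cannot be assigned with certainty. Columns were tied to samples by the column names, which stand in the sample descriptions. Of the symbols, 20858 matched a current mouse symbol and 23062 (99.0%) matched a current symbol, an older symbol or a synonym. No coordinates were used.

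Total counts per library were 18907837, 20093838 and 16948971 in control replicates 1, 2 and 3, and 16506401, 14460621 and 13335328 in p63KO replicates 1, 2 and 3. A count of 3 corresponded to between 0.153 and 0.223 CPM (counts scaled to a common library size), and 3 counts over a group were used as the floor for genes with no count in that group. Ratios of genes with 1 to 3 counts in a group are given with an exact 95% interval, which covers counting error only. No 2 libraries of a group agreed within sampling noise, since the chi-square per degree of freedom between them lay between 7.87 and 16.1.

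Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 13849 of the 18572 genes with a count in any library. Libraries were scaled by the TMM method, and p63KO was compared with control by the edgeR quasi-likelihood test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called changed. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM values are TMM-scaled and given as mean ± SD over 3 libraries.

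The 25 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Of the lists, 24 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over those lists. Each was tested again with an estimated correlation and with fry. None of the 26 listed mitochondrial transcripts had a row in the count table, so that list was not tested. Named genes were Trp63, the 5 largest changes in each direction among changed genes with no overlap between groups and a mean of at least 10 CPM in the higher group (clone and model names left out), the 3 members with the lowest p of each of 9 main lists, the 1 with the lowest p of each other list, and the most abundant member of the ciliated, neuroendocrine, basal and blood lists. A list member outside this rule is named to say which members moved against their list or did not pass, and every other gene named was chosen after its values were seen. Some single-gene results are not reported here, while the counts and medians of the lists include those genes.

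The tests were tried on simulated counts with known changed genes. For p63KO against control, 13457 genes were run, of which 67 were changed 1.5-fold, 67 2-fold and 66 4-fold. Of these, edgeR recovered 50.7%, 79.1% and 95.5%, and it called 4 unchanged genes. Far fewer genes changed than the 4098 called in the data, so these recovery shares and false calls do not carry over directly.

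Alternatives were DESeq2 1.42.0, 2 other scalings, limma-voom, no filter, a filter of 1 CPM in 3 libraries, robust dispersions, the replicate number as a block, each library left out, removal of haemoglobin and sex-linked genes, each list without shared genes, and stricter thresholds. A fit with the level of Y-linked genes as a covariate and the counts of list members without each library were added after the data had been seen.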

Results

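Gene expression was compared between p63KO and littermate control esophageal epithelium at stage E12.5, to ask which genes depend on p63, the transcription factor of stratified epithelia, while the esophageal lining forms. Each group had 3 libraries. Total counts lay between 16948971 and 20093838 in control and between 13335328 and 16506401 in p63KO.

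Trp63 itself was 602.9 ± 63.9 CPM in control and 71.4 ± 8.03 CPM in p63KO (SD, n = 3 each). It was 583.9, 674.1 and 550.6 CPM in the control libraries and 76.7, 62.2 and 75.4 CPM in the p63KO libraries, so every library matched its label. The log2 fold change was -3.08 (SE 0.11), which left 11.8% of the control level. The allele is a knock-in, and the position of the remaining reads within the gene was not analysed here.

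Genes of the basal and squamous epithelium and of its anchorage to the basement membrane fell in p63KO, while 40 of 42 tested genes of neuroendocrine cells rose. The set test of the neuroendocrine list no longer passed with an estimated correlation (camera adjusted p = 0.073), and 8 of its 50 genes had too few counts to test. In the edgeR quasi-likelihood test, 4098 of 13849 tested genes changed, 2113 of them higher and 1985 lower in p63KO. At least 2-fold changes were found for 928 higher and 684 lower genes. The 2 groups did not overlap for 6102 genes (44.1% of those tested), where chance gives 10%. The first principal component held 77.3% of the variance and separated the groups, and the second (8.53%) set control replicate 3 apart from the other libraries. The biological coefficient of variation was 12.7%.

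The 5 largest falls were of Col17a1, Cbr2, Th, Slc7a10 and Vsig8. Col17a1, a transmembrane collagen of the hemidesmosome, fell from 296.9 ± 59.8 to 1.61 ± 1.08 CPM (log2 fold change -7.47, SE 0.31). Th, the tyrosine hydroxylase of catecholamine synthesis, fell from 56.9 ± 10.6 to 0.50 ± 0.23 CPM. Cbr2, a carbonyl reductase, the amino acid transporter gene Slc7a10 and Vsig8 had log2 fold changes of -7.18, -6.52 and -6.47. Each of these calls was kept with 1 library left out, while Vsig8 ranged from -8.02 to -5.98 and Cbr2 from -7.97 to -6.68. The 5 largest rises were of Cnpy1, Neurog3, Gad1, Kirrel2 and Insm1. Insm1, a zinc finger factor of endocrine and neuronal differentiation, rose from 0.84 ± 0.29 to 168.8 ± 25.8 CPM (log2 fold change 7.65, SE 0.20). Neurog3, the proendocrine basic helix-loop-helix factor, had 3 counts in the control libraries together and 1752 in p63KO, a depth-scaled ratio of 718.5 (95% interval 245.5 to 3488). Gad1, which makes the transmitter GABA, had 1 count against 477, a ratio of 586.9 (95% interval 104.8 to 23229). Kirrel2 had 2 counts against 449, a ratio of 276.2 (95% interval 76.0 to 2288). Cnpy1 had no count in control and 450 in p63KO, at least 184.6-fold higher with control set to the floor of 3 counts over the group.

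**Figure D1:**
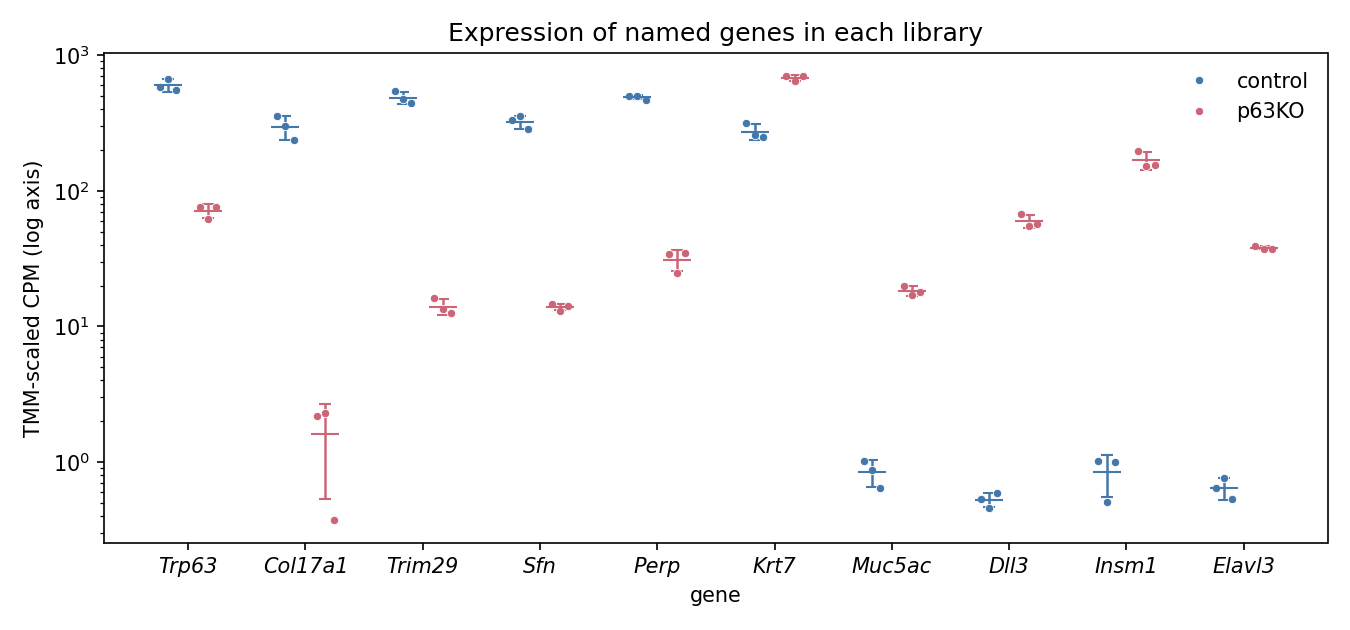
TMM-scaled CPM on a log axis for 10 named genes, with 1 point per library, horizontal bars for group means and error bars for the SD of 3 libraries (control blue, p63KO red). Trp63, Col17a1, Trim29, Sfn and Perp lie lower in all p63KO libraries than in any control library, and Krt7, Muc5ac, Dll3, Insm1 and Elavl3 lie higher.

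Of 39 tested genes of the basal and squamous epithelium list, 26 fell, 1 rose and 12 did not pass the test; adjusted over the list alone, 28 fell and 1 rose. The median log2 fold change was -1.38, and the list stood below other genes (camera adjusted p = 5.4e-32, and adjusted p = 0.046 with an estimated correlation). Fat2, a giant cadherin, fell from 102.3 ± 5.84 to 5.77 ± 0.33 CPM. Trim29 fell from 487.8 ± 48.8 to 14 ± 1.93 CPM and Sfn, the 14-3-3 sigma gene of keratinocytes, from 323.3 ± 36.0 to 13.9 ± 0.79 CPM. Igfbp5, the most abundant member, fell by 0.43 on the log2 scale (SE 0.09) and stayed at 7484 ± 569 CPM. Grhl1 was the member that rose (log2 fold change 1.39). Krt14 did not pass (-1.35, SE 0.71, edgeR adjusted p = 0.20).

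In the hemidesmosome and epithelial basement membrane list, 18 of 21 tested genes fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. Its median log2 fold change was -1.58 (camera adjusted p = 5.1e-38, and adjusted p = 0.046 with an estimated correlation). Col7a1, the anchoring fibril collagen, fell from 177.1 ± 25.2 to 5.36 ± 1.0 CPM. Lama3, a laminin chain, and Col4a6, a basement membrane collagen, had log2 fold changes of -3.36 and -3.91. Fras1 was the member that rose (0.42, SE 0.06), and Itgb1 was at 0.01 and Npnt at -0.11.

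Of 11 tested desmosome genes, 7 fell, 1 rose and 3 did not pass; adjusted over the list alone, 8 fell. The median log2 fold change was -0.90 (camera adjusted p = 2.8e-06). The list no longer passed with adjusted p = 0.087 with an estimated correlation. Perp, a desmosomal membrane protein and p63 target, fell from 491.3 ± 18.6 to 31.1 ± 5.58 CPM. The cytoskeletal linkers Dsp and Jup fell, with log2 fold changes of -0.78 and -0.73. Pkp2, a plakophilin also used outside stratified epithelium, rose (1.06, SE 0.11).

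Of 40 genes reported as p63 targets, 24 fell, 4 rose and 12 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was -0.99 (camera adjusted p = 1.2e-25, and adjusted p = 0.046 with an estimated correlation). The list shares 26 genes with others, Perp, Sfn and Trim29 among them. Those that rose were Chd7 (log2 fold change 1.01), Fras1 (0.42), Sox4 (0.39) and Cdkn1a (0.34). Ezh2 was at -0.05 and Sox2 at -0.15, neither past the test.

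Of 42 tested neuroendocrine genes, 40 rose and none fell, with the same counts adjusted over the list alone. The other 8 of the 50 listed genes had too few counts to test. Genes near 0 in control, such as Neurog3, passed the filter only through their p63KO counts, which favours rises in this tally and in the set tests. Among the untested genes, Scg2 had 0 counts in control and 42 in p63KO and Pax4 had 1 and 38. Fev (6 and 2), Grp (4 and 2) and Resp18 (3 and 1) did not rise. The median log2 fold change was 3.60. The list passed camera (adjusted p = 6.7e-55) and fry (adjusted p = 0.00056), and had adjusted p = 0.073 with an estimated correlation. Dll3, an inhibitory Notch ligand of neuroendocrine cells, rose from 0.53 ± 0.06 to 59.8 ± 6.60 CPM, beside Insm1 and Neurog3. Meis2, the most abundant member, rose by 0.57 on the log2 scale (SE 0.12), from 205.1 ± 35.3 CPM. The members that did not pass were Ghrl, the ghrelin gene (1.14, SE 0.53), and Rfx6, an endocrine transcription factor (0.73, SE 1.2). Rfx6 was 14.1 CPM in control replicate 3, 0.05 and 0.10 CPM in the other control libraries and between 6.02 and 9.27 CPM in p63KO. Without control replicate 3, the log2 fold change of Rfx6 was 6.50 (edgeR adjusted p = 4.6e-06), and 43 of 44 tested members of the list rose. The lowest counts with 1 library left out were 37 of 42 without p63KO replicate 1 and 38 of 42 without p63KO replicate 3.

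**Figure D2:**
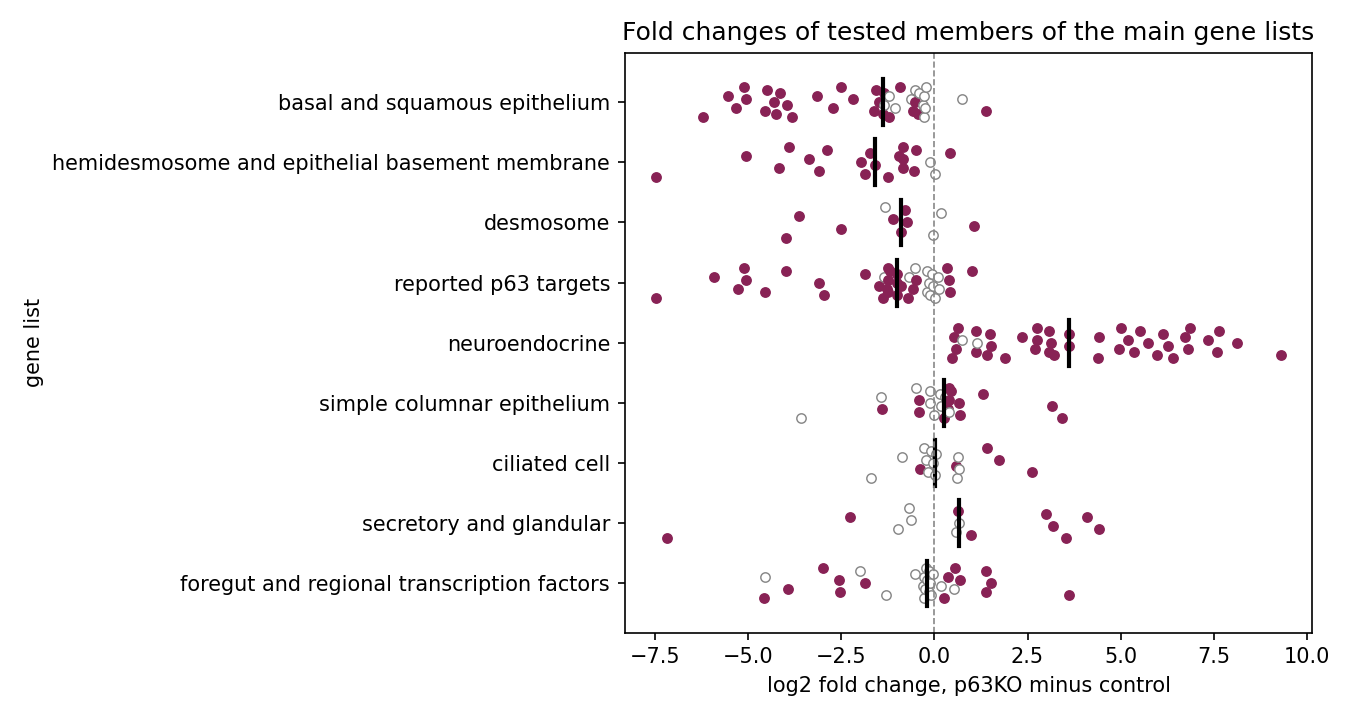
Log2 fold change (p63KO minus control) of each tested member of the 9 main gene lists, 1 point per gene; filled points had an edgeR adjusted p under 0.05, open points did not, and black bars are list medians. The neuroendocrine members lie to the right of 0 (median 3.60), and most members of the basal, hemidesmosome, desmosome and p63 target lists lie to the left (medians -1.38, -1.58, -0.90 and -0.99).

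Among 23 tested genes of simple columnar epithelium, 10 rose, 3 fell and 10 did not pass; adjusted over the list alone, 11 rose and 3 fell. The median log2 fold change was 0.25 (camera adjusted p = 0.023). The call was lost, with adjusted p = 0.77 with an estimated correlation. Krt7, a keratin of simple epithelia, rose from 273.7 ± 35.0 to 681.2 ± 31.3 CPM. The mucin gene Muc1 rose by 3.17 and Tspan1 by 3.42 on the log2 scale. Cdh1, Cldn4 and Ehf were the members that fell. Without control replicate 3, 16 of 23 rose, and without control replicate 2 the set test had an adjusted p of 0.11.

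The ciliated list did not pass as a set (camera adjusted p = 0.33, and 0.94 with an estimated correlation). Of its 46 listed genes, 29 were not tested, so the result covers the 17 tested members only. Of these, 4 rose, 1 fell and 12 did not pass, and adjusted over the list alone 4 rose and 3 fell. The members that rose were Rfx3, a ciliary transcription factor and the most abundant member (log2 fold change 0.57, SE 0.07), Tekt2 (1.73), Tppp3 (2.62) and Rsph9 (1.41). Rfx2 fell (-0.40, SE 0.13), and Foxj1, the master regulator of motile cilia, was at -0.87 (SE 0.30, edgeR adjusted p = 0.058). The Rfx2 call was lost without control replicate 1 or 2 (edgeR adjusted p = 0.15 and 0.065) and without p63KO replicate 1, 2 or 3 (0.076, 0.14 and 0.095).

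The secretory and glandular list had 7 genes that rose, 2 that fell and 5 that did not pass of 14 tested, with the same counts adjusted over the list alone (camera adjusted p = 0.63). Muc5ac, a secreted gel-forming mucin, rose from 0.85 ± 0.19 to 18.3 ± 1.44 CPM. Cbr2 and Sox9 fell, Sox9 from 190.0 ± 18.5 to 39.6 ± 2.88 CPM. The other 18 listed genes were not tested. Without p63KO replicate 1 or 3, 5 members rose, and without control replicate 2 or p63KO replicate 2, 6 rose. Without control replicate 2, 3 members fell.

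Of 31 tested foregut and regional transcription factors, 8 rose, 6 fell and 17 did not pass; adjusted over the list alone, 8 rose and 9 fell (camera adjusted p = 0.78). Tbx1, a factor of the pharyngeal endoderm, fell from 45.8 ± 6.0 to 5.77 ± 1.32 CPM. Isl1, a LIM homeodomain factor, rose from 2.16 ± 0.60 to 26.2 ± 6.32 CPM, and Hoxb4 rose from 20.5 ± 2.59 to 59.0 ± 3.40 CPM. Foxe1 fell by 2.54 and Hoxa5 rose by 1.37 on the log2 scale. Sox2, the foregut factor, was 643.6 ± 92.8 CPM in control and 581.8 ± 29.9 CPM in p63KO (log2 fold change -0.15, SE 0.10, edgeR adjusted p = 0.33). Without control replicate 3, 7 of 30 rose and 10 fell.

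Signalling genes moved in both directions. Of 27 tested Notch pathway genes, 9 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.088, and 0.044 without p63KO replicate 3). The ligand genes Dll3 and Dll1 rose and Jag2 and Jag1 fell (log2 fold changes -2.97 and -1.0). Of the receptor genes, Notch3 rose (0.37) and Notch1 and Notch2 fell (-0.91 and -0.34), and the effector Hes1 fell (-1.02). Of 34 Wnt pathway genes, 16 fell and 5 rose, also over the list alone (camera adjusted p = 4.0e-05). The Wnt list had adjusted p = 0.12 with an estimated correlation. Dkk3 fell from 50.6 ± 1.83 to 13.1 ± 1.41 CPM; the members that rose were Axin2, Nkd1, Sp5, Notum and Wif1, while Lgr5, Rnf43, Tcf7 and Nkd2 were among those that fell. Without p63KO replicate 1, 3 Wnt members rose. Of 38 BMP, Hedgehog and FGF genes, 10 rose and 7 fell, also over the list alone. Bmpr1b, a BMP receptor, rose from 16.3 ± 0.29 to 42.6 ± 2.99 CPM, and the set had a median of -0.17, a mean of 0.05 and a camera adjusted p of 0.96 in the upward direction.

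Most chromatin and cell cycle genes did not pass the test, and those that did moved in both directions. Of 32 chromatin modifier genes, 5 rose, 1 fell and 26 did not pass, and over the list alone 3 rose and 1 fell (camera adjusted p = 0.84). Uhrf1, needed to maintain DNA methylation, fell from 322.3 ± 24.3 to 233.5 ± 19.7 CPM. Only 2 chromatin members rose without control replicate 1, and 3 without control replicate 2, p63KO replicate 1 or p63KO replicate 3, while 2 fell without control replicate 3, p63KO replicate 1 or p63KO replicate 2. Of 42 cell cycle genes, 3 rose and 8 fell, and over the list alone 3 rose and 5 fell (camera adjusted p = 0.35). Ccnd2, a G1 cyclin, fell from 1881 ± 158 to 964.7 ± 85.9 CPM. The number of cell cycle genes that fell was 3 without control replicate 2, 4 without p63KO replicate 1 or 3, and 5 without p63KO replicate 2; 1 rose without p63KO replicate 3. Of 24 cell cycle inhibitor and p53 response genes, 5 rose and 6 fell, and over the list alone 6 rose and 6 fell; the median was 0.12, the mean -0.01 and the camera adjusted p 0.63. Btg2, an antiproliferative p53 target, rose from 133.4 ± 16.4 to 413.9 ± 30.8 CPM. Without control replicate 3, 3 of these rose, and without p63KO replicate 1, 8 rose.

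Most stress and interferon genes did not pass the test, and those that did also moved in both directions. Over all tested genes, 4098 of 13849 changed. Of 24 stress and dissociation genes, 2 rose and 1 fell, and over the list alone 1 rose and 1 fell (camera adjusted p = 0.63). Atf4, of the integrated stress response, rose by 0.40 on the log2 scale (SE 0.07). Of 17 interferon and antigen presentation genes, 2 rose and 4 fell, and over the list alone 2 rose and 5 fell (camera adjusted p = 0.16, and 0.037 without p63KO replicate 1). Ifitm3, an antiviral membrane protein, fell from 125.7 ± 9.27 to 18.6 ± 4.97 CPM. The stress members that rose numbered 1 without control replicate 1 or control replicate 3 and 4 without control replicate 2, and 2 stress genes fell without p63KO replicate 2. Without control replicate 1 or 2 or p63KO replicate 1 or 3, 1 interferon gene rose.

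Markers of other cell types were measured beside these groups. Of 29 mesenchyme genes, 12 fell and 4 rose, and over the list alone 15 fell and 4 rose (median -0.81, camera adjusted p = 0.60). Tbx18 rose from 6.51 ± 1.43 to 62.6 ± 5.89 CPM, and Dcn, Fn1 and Twist1 also rose. Of 15 muscle genes, 6 fell and 1 rose, also over the list alone (camera adjusted p = 0.33). The muscle gene that rose was Pax3, from 0.07 ± 0.04 to 6.85 ± 2.17 CPM. The number of mesenchyme genes that fell was 5 without control replicate 1. For muscle it was 3 without control replicate 1 or p63KO replicate 1 and 2 without p63KO replicate 3, and 2 muscle genes rose without p63KO replicate 2. Of 19 enteric neuron and neural crest genes, 6 rose and 3 fell, and over the list alone 6 rose and 4 fell (camera adjusted p = 0.0015). The list had adjusted p = 0.65 with an estimated correlation and 0.28 with limma-voom. Elavl3, a neuronal RNA-binding protein, rose from 0.65 ± 0.12 to 38.0 ± 1.09 CPM, Tubb3, Elavl4, Stmn2, Stmn3 and Ret rose with it, and Th, Gfra1 and Ednrb fell.

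Of 10 tested endothelial genes, 1 rose, Flt4 (log2 fold change 1.63, SE 0.50), and over the list alone none changed (camera adjusted p = 0.93). The Flt4 call was lost without control replicate 3 (edgeR adjusted p = 0.052) and without p63KO replicate 1, 2 or 3 (0.063, 0.11 and 0.086). Of 11 blood genes, 1 fell, Epor (-1.03, SE 0.28), and over the list alone none changed (camera adjusted p = 0.93). The Epor call was lost without control replicate 1 or 2 (0.053 and 0.078) and without p63KO replicate 2 or 3 (0.078 and 0.079). Hbb-y, the most abundant blood gene, did not differ past the test (0.03, SE 0.85, edgeR adjusted p = 0.99), whereas without control replicate 3 it was higher by 2.05 (adjusted p = 0.013) and 2 blood genes rose. Of 8 genes of trachea, lung, thyroid, liver and cartilage, 3 rose and 2 fell, and over the list alone 3 rose and 3 fell; the median was 0.60, the mean 0.05 and the camera direction downward (adjusted p = 0.76). Col9a3, a cartilage collagen, fell from 34.0 ± 5.97 to 3.63 ± 0.21 CPM.

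Among 6 tested sex-linked genes, 1 fell, Tsix, an antisense transcript of Xist (log2 fold change -2.89, SE 0.63, also over the list alone; camera adjusted p = 0.69). With 1 library left out, Tsix ranged from -4.12 (without p63KO replicate 2) to -2.38 and stayed lower in each fit. Xist was 1.59 CPM in p63KO replicate 2 and between 514.4 and 1456 CPM in the other 5 libraries. The Y-linked gene Ddx3y was 104.9 CPM in p63KO replicate 2 and between 33.8 and 75.4 CPM in the others, so those 5 libraries held both Xist and Y-linked RNA. Their values argue against 1 embryo as the only source of each of those 5 libraries. The number of embryos per sample is not given.

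In control replicate 3, 58 genes were above 5 CPM and over 4 times the highest other library plus 1 CPM, against 2 in control replicate 1 and 0 in each other library. Gata4 was 69.9 CPM in control replicate 3 and at most 0.24 CPM elsewhere, and Cdx2, an intestinal transcription factor, was 54.1 CPM and at most 0.10 CPM. These genes were chosen after their values were seen. Gata4 and Cdx2 were left out by the filter, which needs enough counts in more than 1 library.

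**Figure D3:**
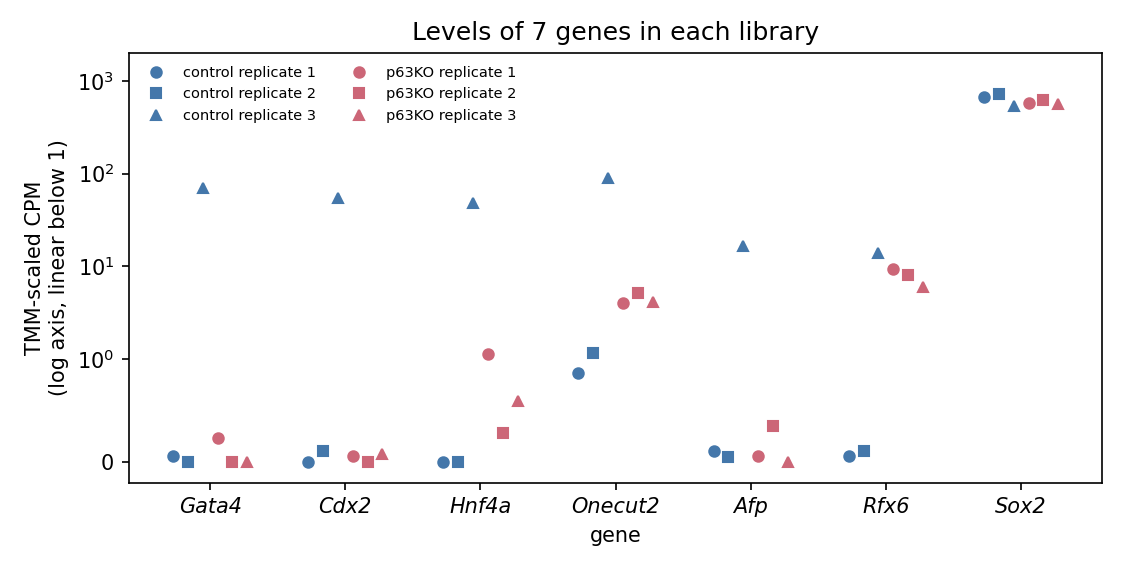
TMM-scaled CPM (log axis, linear below 1) of 7 genes, chosen after their values were seen, with 1 point per library and symbols for the replicate number (control blue, p63KO red). Gata4, Cdx2, Hnf4a, Onecut2 and Afp are highest in control replicate 3 (69.9, 54.1, 48.6, 90.3 and 16.6 CPM), whereas Sox2 lies between 538.9 and 716.0 CPM in all 6 libraries.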

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

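The fit with the Y-linked level as a covariate was chosen after the data had been seen. The count of changed genes, 4098, lay between 4002 and 4108 under other scalings, filters and tools (4039 with DESeq2, 4082 with limma-voom), between 3150 (without p63KO replicate 3) and 3771 (without control replicate 3) with 1 library left out, and at 3713 with the Y-linked level as a covariate. It was 2580 at an adjusted p under 0.01 and 1612 with at least a 2-fold change, by construction of those thresholds. No setting called a gene in the opposite direction. Scaling moved the median of all genes by at most 0.02 (log2). Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave as many genes (4098, and 0 as the highest of the others); the splits are too few for a share under 0.05.

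Samples with the same replicate number had correlations of their deviations of 0.17, 0.26 and 0.03, and the last is under the bound of 0.1, so the numbers were not taken to pair the samples. As a hint from the data, 5 of 6 samples correlated best with their own number, and control replicate 3 did so with p63KO replicate 1 (0.06). With the replicate number as a block, 4778 genes changed, 2397 higher and 2381 lower.

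Among the main lists, an estimated correlation ended the calls of the desmosome (adjusted p = 0.087), neuroendocrine (0.073) and simple columnar lists (0.77). The simple columnar list also missed the threshold with fry (0.052) and without control replicate 2 (0.11, range 0.00079 to 0.11 with 1 library left out). In fry's test for change in either direction, the ciliated (5.0e-05), secretory (8.6e-06) and foregut lists (1.9e-05) passed. Directions turned only where no call was made. The foregut list turned with the stricter filter (0.99). The BMP, Hedgehog and FGF list turned with upper-quartile factors (0.94), limma-voom (0.94), no filter (0.99), the replicate block (0.998), the Y-linked covariate (0.998) and libraries left out (range 0.81 to 0.98, with 0.85 without control replicate 2, 0.91 and 0.96 without p63KO replicates 2 and 3). Endothelium turned with the stricter filter (0.94) and without control replicate 2 (0.97), blood with limma-voom (0.99) and without control replicate 3 (0.68), the neighbouring tissues with limma-voom (0.80) and stress without control replicate 3 (0.96). With 1 library left out, the adjusted p of the endothelium, blood and stress lists ranged from 0.71 to 0.97, from 0.50 to 0.97 and from 0.15 to 0.96. With 1 library left out, Hbb-y ranged from -0.50 to 2.05, and Neurog3 and Gad1, with few control counts, from 8.73 to 10.1 and from 8.23 to 10.4. The cause was not tested. With 3 libraries per group, 50.7% of simulated 1.5-fold changes were recovered, in a simulation with far fewer changed genes than these data. Small changes can be missed, but that share does not carry over directly.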

Other observations

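The genes in the next 2 paragraphs were chosen after their values were seen, so their tallies are no test of a group. Of the tests below, those of glandular stomach and intestinal genes in p63KO and of the tuft list without Hpgds were chosen after the result was seen, and that of control replicate 3 was chosen after the pattern had been seen in other genes.

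Of 12 genes, 4 of them in the neuroendocrine list and most picked for known roles in endocrine cells, 11 rose in p63KO and Rfx6 did not pass the test. Myt1, a zinc finger factor of endocrine progenitors, rose from 0.40 ± 0.19 to 33.0 ± 3.84 CPM, Nkx6-1 from 4.2 ± 1.84 to 19.3 ± 9.66 CPM and the forebrain factor Fezf2 from 0.63 ± 0.20 to 9.01 ± 6.45 CPM (SD, n = 3). The subunits of the ATP-sensitive potassium channel both rose, Abcc8 from 2.91 ± 1.63 to 44.1 ± 11.8 CPM and Kcnj11 from 2.25 ± 0.32 to 20.4 ± 7.96 CPM. Ptprn2, a dense-core vesicle protein, rose by 7.10 on the log2 scale. Of 13 genes picked for roles in excitability and vesicle release, all 13 rose, with log2 fold changes from 0.45 for Stx1a, 1.08 for Rab3a and 1.10 for Cacna1h to 5.93 for Kcnh6. The hormone genes Sst and Calca rose too, to 1.58 ± 0.71 and 1.95 ± 0.74 CPM in p63KO, where Insm1 was 168.8 ± 25.8 CPM. Other listed hormone genes did not: Ghrl did not pass the test. Calcb (3 counts in control and 3 in p63KO), Grp (4 and 2) and Gast (0 and 0) had too few counts to test.

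Of 7 genes of monoamine and GABA synthesis or transport, 6 rose and Th fell (log2 fold change -6.83). Those that rose were Gad1, Tph1 (0 counts in control and 54 in p63KO), Ddc (2.77), Gch1 (3.88), Slc6a4 (2.57) and Slc18a1 (1.49). Snai2 and Zeb2, known as regulators of epithelial-mesenchymal transition, fell from 37.8 ± 5.95 to 1.21 ± 0.73 CPM and from 25.9 ± 3.93 to 2.73 ± 0.77 CPM. Of the related genes looked at with them, Cdh2 rose (log2 fold change 1.0), and Zeb1 (-0.44) and Vim (-0.13) did not pass the test. Yap1 fell by 0.70 on the log2 scale and Rest, a repressor of neuronal genes, by 0.44. In the Myc family, Mycn rose (1.34) and Myc and Mycl1 fell (-1.32 and -1.03).

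The rise of the neuroendocrine list was set against more enteric neurons or neural crest cells in the p63KO isolations, since Elavl3, Tubb3 and Ret are shared by enteric neurons. Of 12 markers of those cells that are not general neuronal genes, 10 were tested, with a median log2 fold change of -0.81 (quartiles -1.29 and 0.05), far under the median of 3.99 of the neuroendocrine genes that rose and under the bound of 1.0 that counts against the explanation. Ret was the exception at 4.84, and Sox10 was at -1.34. These values argue against such cells as the source of the rise. A change within the epithelium stays open as a hypothesis, which may also involve a rare cell type that these bulk data do not resolve.

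The fall of basal genes was set against a lower share of epithelium in the p63KO isolations. Of 14 pan-epithelial genes, the median log2 fold change was 0.17 (quartiles -0.17 and 0.31), against -2.94 for the basal and squamous genes that fell. Of the mesenchyme genes, 12 fell and 4 rose, and their summed level was 1727 to 1915 CPM in control and 2896 to 3375 CPM in p63KO, with Dcn at 159.0 and 1222 CPM. The pan-epithelial median argues against a lower share of epithelium as the cause of the fall, while the rise of Dcn, Fn1, Tbx18 and Twist1 stays open. A loss of basal identity in the epithelium remains a hypothesis found on these data, and it was not itself tested.

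Tbx1 and Foxe1 fell while Hoxa5 and Hoxb4 rose, so the p63KO isolations may have been cut further towards the stomach. The other 12 tested Hox genes had a median log2 fold change of 0.62, with 8 higher and none lower in the edgeR test (adjusted p under 0.05), which lies between the bound that would have counted against this (0.36) and the one that would have counted for it (0.72). Hoxb6 (3.82, SE 0.91) and Hoxb5 (3.17, SE 0.25) rose most of the 12, and Hoxc8 was lowest (-0.66, not past the test). A cut at another level and an effect of p63 on regional genes cannot be told apart. The median of the tested stomach genes was -3.67, under the bound of 0.25 written before these genes were looked at, but that bound was not usable, since 2 genes were tested and control replicate 3 decided the value (2.11 for Onecut2, the 1 gene tested without it). Of 11 glandular stomach and intestinal genes, none exceeded 1.26 CPM in a p63KO library. Gkn1, Gkn2, Gkn3, Tff1, Tff2, Cdx1 and Pdx1 were at most 2.47 CPM in control replicate 3 too and cannot decide. Gata4, Cdx2, Hnf4a and Hnf4g were 8.83 to 69.9 CPM there and at most 1.12 CPM in p63KO. Their values argue against such epithelium in p63KO in an amount that gives the levels of control replicate 3. Vil1 was 3.94 to 7.08 CPM in p63KO and 0.43 and 0.46 CPM in control replicates 1 and 2. Cdh17 and Onecut2 were higher than in those controls too. A small share and forestomach stay open.

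That the 58 genes of control replicate 3 may come from stomach or intestinal epithelium was tested as a hypothesis. A list of 20 intestinal and gastric genes was fixed before their values were looked at but after Gata4, Cdx2 and Hnf4a had been seen, and 6 of its genes also belong to the fixed gene lists. Of the 19 with at least 20 counts, 12 (63.2%) were over 4 times higher in control replicate 3 than in each other library. They were led by Apob (128.0 CPM), Lgals2 (32.6 CPM) and Isx (27.4 CPM). Unlike the rule for the 58 genes, this count set no minimum CPM, so low genes such as Fabp1 (1.18 CPM) and Apoa4 (1.41 CPM) are in it. By the stricter rule, Apob, Lgals2, Isx and Cdh17 passed. Genes could also reach 20 counts through control replicate 3 alone, so the share does not decide the hypothesis. Afp at 16.6 CPM also fits yolk sac or liver RNA, which was not tested apart.

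A rise of tuft cell genes in p63KO was tested as a hypothesis. Of 19 listed genes, 5 were tested; the camera p was 0.15, downward, while the median log2 fold change was 0.35. The direction rested on Hpgds (-5.59), and without it the direction was upward, also not past the threshold. Dclk1 and Trpm5 rose (1.26 and 1.2), and Avil and Ptgs1 did not pass (0.24 and 0.35). The written bound, a p of 0.05 or more or a downward direction, was met but not usable with 5 genes and 1 of them setting the direction, so the hypothesis was left undecided.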
